A study of Mus musculus with 8 samples.

How the data were processed

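Gene expression was measured on the Affymetrix Mouse Gene 2.1 array in 4 groups of mouse samples with 2 arrays each, 8 arrays in all. Per the labels, RNA was amplified and biotin-labelled with NuGEN kits. The column kit used for RNA extraction was the same for the 3 kinds of cultured cells and another one for the inner cell mass. The values used here are those the authors deposited, 1 per probe set and array. They were made with Affymetrix Expression Console 1.3.1, per the submitters' processing notes. The summarisation algorithm, the background correction and the library files are not given in the sources used here. The deposited values ran from about 2 to about 12 in every column, from which they were read as log2 intensities: a natural or decimal logarithm would place the brightest probe sets above what a 16-bit scanner records. Array medians lay between 4.16 and 4.28, so the arrays had been brought to a common scale but not to identical distributions. The deposited log2 values were used without further normalization.

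Of the 41345 probe sets, 23521 were listed with 1 gene in the platform annotation, 1814 with several and 16010 with none. Genes were named only from probe sets with 1 gene. Of these symbols 23328 were found in the mouse RefSeq gene table, which updated 0 of them, and the others kept the annotation's symbol. Coordinates are not given because no genome build is stated for the values. Where a gene had several probe sets (1082 of 22180 genes), the one with the highest mean over all 8 arrays stood for it. A gene was tested if it was above the median of all values, 4.24, on at least 2 arrays. That left 13597 genes, and 8583 were not tested. The 657 genes with several tested probe sets show how far these differ: of 58 such genes with any probe set past the threshold between FGF-ESC and ESC, 21 had all of them past it. Opposite calls from probe sets of 1 gene arose for 1 gene, Zfp979, between EpiSC and ICM, and for 0 genes in the other 5 comparisons.

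The groups were compared with limma 3.58.1 in R 4.3.3. A means model was fitted to all 8 arrays (lmFit, contrasts.fit and eBayes with default settings), so that the 4 groups shared 1 estimate of the spread with 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each of 6 comparisons. A gene passed at an adjusted p below 0.05 and a log2 fold change of at least 1 in either direction. Every adjusted p and SE given for a gene is limma's. The SE comes from the spread pooled over all 4 groups, not from the 2 groups compared. It can therefore understate the spread of FGF-ESC, whose residual SD was the largest, 0.279 against 0.124 in ESC. Nothing in the labels says that the 2 arrays of a group came from separate cultures or separate embryo pools, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

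Gene lists, the comparisons, the thresholds, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated. There were 33 lists with 690 entries, of which 627 matched a named gene and 540 were tested. A gene could be on several lists, so lists that share genes are not separate lines of evidence. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, over lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation, and fry, a rotation test of whether a list's genes move on balance in 1 direction, stood beside it. With an estimated correlation, camera also tests on the 4 residual degrees of freedom, which by itself raises its p-values. Of the lists that passed camera between ESC and EpiSC, 1 held with an estimated correlation, and 0 did in the comparisons of FGF-ESC with ESC, EpiSC and ICM. Named genes are, for each comparison of FGF-ESC, the 8 largest rises and 8 largest falls past the threshold without overlap between the groups' arrays, a panel of 16 marker genes, and up to 4 members with the smallest adjusted p from each list described. For the other comparisons it was 4 rises, 4 falls, the panel and up to 2 members. One panel gene had no probe set of its own and was not analysed here. The fibroblast list was fixed because FGF-ESC and EpiSC were grown on feeder fibroblasts.

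A position between ESC and EpiSC was computed for each FGF-ESC and ICM array. Axis genes were those that differed by at least 2 on the log2 scale between replicate 1 of ESC and of EpiSC, and positions were measured against replicate 2 of both. The replicates were then exchanged and the results averaged. The value is 0 at ESC and 1 at EpiSC. Correlations between fold changes that share a group were set beside 100 simulations of unchanged groups.

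The code was tested on simulated data with the measured means and spread. In the simulated comparison of FGF-ESC with ESC over 13597 genes, 49 of 50 genes changed by 1.5 on the log2 scale were recovered, and 3 unchanged genes were called. Against EpiSC 47 were recovered with 5 unchanged genes called, and against ICM 47 with 9. A simulated position of 0.3 was recovered as 0.297 and 0.29. The alternatives tried were quantile normalization, centring of each array on its median, no filter and a stricter one, other ways to summarise probe sets, other moderation, array weights, fewer groups in the fit, a replicate block, other thresholds, and each array left out in turn. With 1 array left, a group adds nothing to the shared estimate of the spread, so calls can change although folds do not. Counts of list members without FGF-ESC replicate 1 were added after the data were seen, because that array had the highest fibroblast signal. So were the overlaps with 1 array of the shared group in each comparison.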

Results

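Transcript levels were measured on Affymetrix Mouse Gene 2.1 arrays in 4 groups of C57BL/6J mouse samples, with 2 arrays in each group. FGF-ESC are pluripotent lines grown with FGF2 and 20% serum replacement on embryonic fibroblast feeders, and EpiSC, which stand for the primed epiblast state, were grown in the same kind of medium, also on feeders. ESC, the naive reference, were grown with LIF and a pair of kinase inhibitors and without feeders. The sample labels add 15% serum to the ESC medium, which the description of the cultures does not name. ICM is the inner cell mass of uncultured day 3.5 blastocysts, freed of trophectoderm by immunosurgery. The labels give day 3.5 embryos as the origin of all lines, EpiSC included. Medium, feeders and cell type therefore changed together between ESC and the other cultured groups. Across 41345 probe sets, array medians on the log2 scale were 4.16 and 4.25 in FGF-ESC, 4.27 and 4.28 in ESC, 4.26 and 4.23 in EpiSC and 4.23 and 4.26 in ICM. Across the 13597 tested genes, which are not independent replicates, the arrays of a group correlated at r = 0.968 in FGF-ESC, 0.994 in ESC, 0.991 in EpiSC and 0.983 in ICM. The FGF-ESC arrays differed from each other by at least 1 on the log2 scale for 395 genes, against 0 in ESC, 20 in EpiSC and 80 in ICM. A group mean under the median of all values, 4.24, is near background, so a fold against it depends on that floor. For FGF-ESC this held for the lower group in 7 of the 8 largest rises named against ESC, 4 of 8 against EpiSC and 8 of 8 against ICM, and in 0, 4 and 7 of the 8 largest falls. For ESC with EpiSC it held in 2 of the 4 largest rises and 3 of the 4 largest falls. The counts were 3 and 4 of 4 for ESC with ICM, and 3 and 2 of 4 for EpiSC with ICM.

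Genes of fibroblasts set the FGF-ESC arrays apart from all others. The mean level of 26 fibroblast marker genes was 8.54 and 7.27 on the FGF-ESC arrays, 4.37 and 4.41 in ESC, 5.09 and 5.32 in EpiSC and 4.33 and 4.46 in ICM. Of these 26 genes, 13 were above the median of all values on both ESC arrays, 20 on both EpiSC arrays and 14 on both ICM arrays. FGF-ESC replicate 1 had the highest level, and gene counts are also given without it, a choice made after the data were seen.

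**Figure D1:**
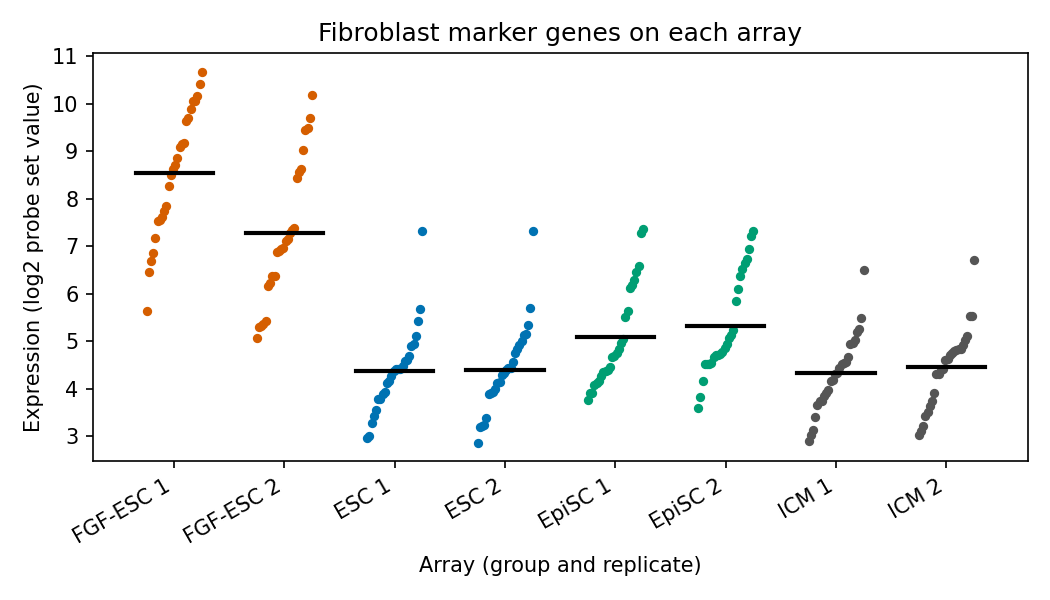
Log2 probe set values of 26 fibroblast marker genes on each of the 8 arrays, with a bar at the mean of each array. The means are 8.54 and 7.27 on the FGF-ESC arrays and at most 5.32 on the others.

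The comparison of FGF-ESC with ESC asks how lines kept in FGF2 differ from naive stem cells of the standard kind. Fibroblast list genes and chemokines were among the largest rises. Col1a2 (probe set 17548532), a chain of type I collagen, was at 10.05 in FGF-ESC and 3.33 in ESC, a log2 fold change of 6.72 ± 0.23 (SE, n = 2 arrays per group, adjusted p = 5.43e-06). The SE pools the spread of all 4 groups, while Col1a2 had an SD of 0.51 in FGF-ESC and 0.14 in ESC. Its other probe set (17455801) was at 8.09 and 4.60, a difference of 3.49. Ccl2, a chemokine that attracts monocytes, rose by 6.86 ± 0.26, the matrix proteoglycans Dcn and Lum by 6.66 ± 0.32 and 6.53 ± 0.28, and the matrix protease Mmp3 by 6.49 ± 0.36. Ifi204, an interferon-inducible gene of a family with near-identical copies and so uncertain, rose by 6.31 ± 0.30, the chemokine Ccl8 by 5.85 ± 0.24 and the annexin Anxa1 by 5.81 ± 0.38. Falls were smaller. The selective autophagy receptor Calcoco2 had a log2 fold change of -2.74 ± 0.15 (adjusted p = 3.71e-05), Epp13 of -2.45 ± 0.14, Lrrc31 of -2.12 ± 0.20, the ephrin receptor Epha4 of -2.06 ± 0.12, the melanosome protein Pmel of -1.97 ± 0.21 and the desmosomal cadherin Dsg2 of -1.95 ± 0.23 (-0.61 on its other, dim probe set). The imprinted zinc finger gene Plagl1 (-1.97 ± 0.40, adjusted p = 0.016) did not pass without ESC replicate 1 (0.106) or ESC replicate 2 (0.11), with a range of 0.00729 to 0.11 over its alternatives, and was at -0.90 on its other probe set. Lrrc34 (-1.93 ± 0.31, adjusted p = 0.00673) did not pass without either of these arrays (0.062 and 0.0662) or in a fit of these groups alone (0.0508), with a range of 9.64e-06 to 0.0662.

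In that comparison 844 genes passed, 717 higher and 127 lower in FGF-ESC. The excess of higher genes depended on the fold minimum, since without it 1256 genes were higher and 831 lower, and on the choice of probe sets, since 781 probe sets were higher and 291 lower when each counted on its own. Of the 26 fibroblast genes, 23 rose and 0 fell (25 and 0 adjusted over the list alone), with a median of 3.37 and a camera adjusted p of 1.04e-25 (adjusted p = 0.397 with an estimated correlation). Thy1, a surface glycoprotein of fibroblasts, rose by 4.42 ± 0.22. When FGF-ESC replicate 1 was left out, 575 genes passed, among them 23 of the fibroblast list, whose median was then 2.55. The number of genes passing changed with the array left out, even for ESC, whose arrays differed by at least 1 for 0 genes. A group left with 1 array adds nothing to the shared estimate of the spread. A call can thus be lost although the fold is kept. For Zfp42 the log2 fold change was -1.265 without ESC replicate 1 and -1.287 without ESC replicate 2.

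**Figure D2:**
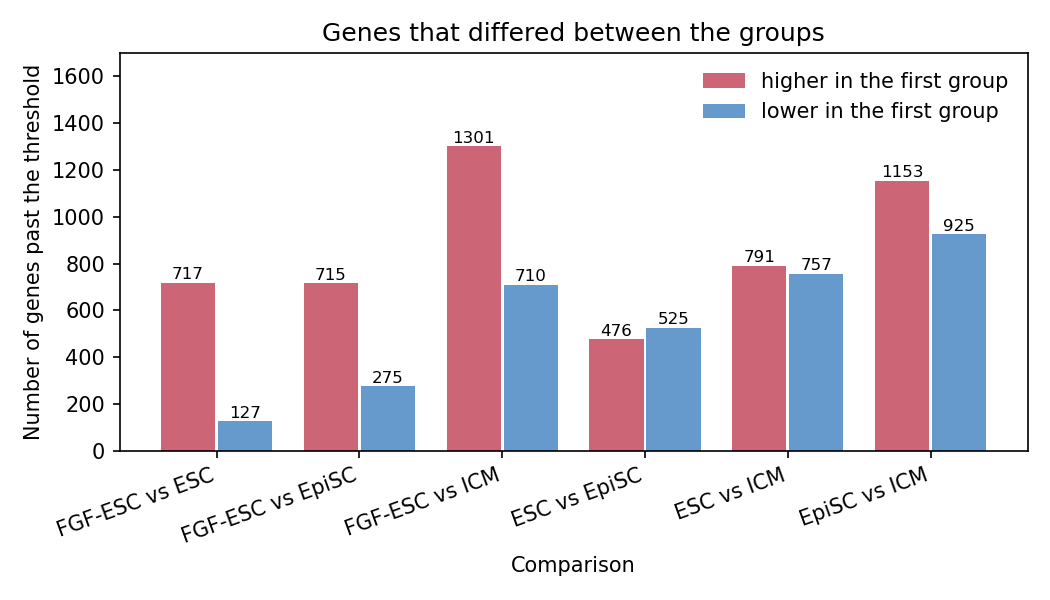
Number of genes past an adjusted p of 0.05 and a log2 fold change of 1 in each of 6 comparisons, split into genes higher and lower in the first group named. FGF-ESC had 717 genes higher and 127 lower than ESC, and 715 higher and 275 lower than EpiSC.

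Naive pluripotency genes were lower in FGF-ESC than in ESC by varied amounts. Tfcp2l1 (probe set 17216620), a transcription factor of naive self-renewal, was at 7.13 in FGF-ESC and 8.88 in ESC, a log2 fold change of -1.75 ± 0.16 (adjusted p = 0.000514). Pecam1, an adhesion molecule, had -1.55 ± 0.18 and Tbx3, a T-box factor, -1.12 ± 0.14 (adjusted p = 0.00215). Klf4 (probe set 17425401), a target of LIF signalling, was nearly level at 8.52 and 8.59, with a change of -0.07 ± 0.13 (adjusted p = 0.752). Of 25 naive genes 0 rose and 6 fell (0 and 6 adjusted over the list alone), with a median of -0.56 and a camera adjusted p of 3.2e-05 (adjusted p = 0.618 with an estimated correlation). The number that fell was 5 without FGF-ESC replicate 1, with a median of -0.41, and 3 without ESC replicate 1. The fibroblast list was higher in FGF-ESC by a median of 3.37 in this comparison.

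Zfp42, known as Rex1, had a log2 fold change of -1.28 ± 0.21 (adjusted p = 0.0076) but did not pass without ESC replicate 1 (0.0747) or ESC replicate 2 (0.0659), with a range of 0.00203 to 0.0747 over its alternatives. Nanog, a core pluripotency factor, was at 9.01 and 9.99, a change of -0.98 ± 0.21 (adjusted p = 0.0193) that was just under the fold minimum and passed without FGF-ESC replicate 2 (-1.34). Dnmt3b, a de novo DNA methyltransferase, was at 8.73 and 7.73, a change of 0.999 ± 0.141 (adjusted p = 0.00358) that was just short of the minimum and passed without FGF-ESC replicate 2 (1.14) or ESC replicate 1 (1.02). Among panel genes that did not pass, Esrrb had -0.55 ± 0.16, Pou5f1 (probe set 17337155) -0.49 ± 0.12 and Prdm14 -0.27 ± 0.20. The Pou5f1 probe set was at 5.95 to 6.57 in the group means. Primed and lineage genes of the panel that did not pass were Fgf5 (probe set 17439517) at 0.22 ± 0.17, Cer1 at 0.34 ± 0.46 and Lefty1 at 0.82 ± 0.16. Sox2 changed sign with the arrays used (-0.19 ± 0.20, and 0.13 without FGF-ESC replicate 1), as did Dppa3 (0.27 ± 0.26, and -0.11 without FGF-ESC replicate 2) and Otx2 (0.21 ± 0.19, and -0.03 without FGF-ESC replicate 2).

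**Figure D3:**
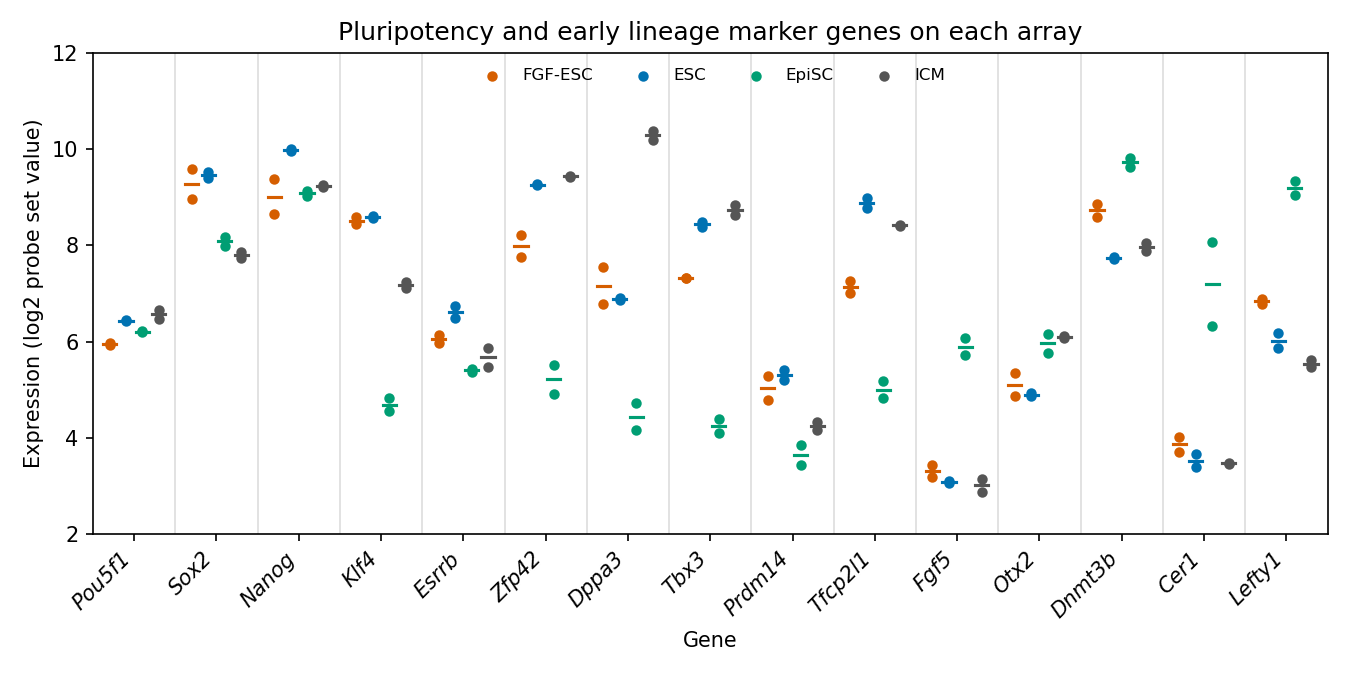
Log2 probe set values of 15 pluripotency and early lineage marker genes, with a point per array and a bar at the mean of each group. Klf4 is near 8.52 in FGF-ESC and 8.59 in ESC against 4.69 in EpiSC, while Fgf5 is at 3.30 in FGF-ESC and 5.90 in EpiSC.

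Targets of FGF and ERK signalling were higher in FGF-ESC than in ESC. Egr1, an immediate early transcription factor, rose by 3.27 ± 0.23 (adjusted p = 0.000149), Dusp6, an ERK phosphatase, by 1.58 ± 0.12 (2.52 on its other probe set), Fos by 2.36 ± 0.23 and Ier3 by 2.58 ± 0.26. Of 19 such genes 10 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 1.09 and a camera adjusted p of 2.16e-10 (adjusted p = 0.397 with an estimated correlation). The count was 5 without FGF-ESC replicate 1, with a median of 0.76, and also 5 without ESC replicate 1 or ESC replicate 2. Primed epiblast genes moved the same way: 5 of 22 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.61 and a camera adjusted p of 2.16e-05 (adjusted p = 0.249 with an estimated correlation). Lef1, a WNT effector, rose by 1.43 ± 0.17 and Sox4 by 2.02 ± 0.27 (1.63 on its other probe set). The primed count was 3 without FGF-ESC replicate 1. The ESC medium held inhibitors of ERK signalling and of GSK3, and fibroblast genes were higher in FGF-ESC by a median of 3.37 beside both lists.

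Genes of antigen presentation and interferon response also rose in FGF-ESC relative to ESC. B2m, the light chain of MHC class I, rose by 2.18 ± 0.12 (adjusted p = 4.92e-05), the immunoproteasome subunit Psmb9 by 2.79 ± 0.18, the interferon regulator Irf7 by 3.51 ± 0.35 and H2-K1, from a family of near-identical copies so that the copy read is uncertain, by 2.15 ± 0.21. Of 16 genes 11 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 2.04 and a camera adjusted p of 1.36e-10 (adjusted p = 0.397 with an estimated correlation). The count was 9 without FGF-ESC replicate 1, with a median of 1.65, and 7 without ESC replicate 1 or ESC replicate 2. Of 15 mesenchymal transition genes, 3 of which are also on the fibroblast list, 10 rose and 0 fell (11 and 0 adjusted over the list alone), with a camera adjusted p of 1.04e-10 (adjusted p = 0.397 with an estimated correlation). Mmp2, a gelatinase, rose by 4.95 ± 0.29, the calcium-binding S100a4 by 5.46 ± 0.33, the transcription factor Snai2 by 3.04 ± 0.27 and the intermediate filament Vim by 2.57 ± 0.24 (3.34 on its other probe set). The mesenchymal count was 8 without FGF-ESC replicate 1, 5 without ESC replicate 1 and 6 without ESC replicate 2. Both groups rose on arrays with a mean fibroblast level of 8.54 and 7.27, against 4.37 and 4.41 in ESC.

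Stress and p53 genes rose in part. Egr1 and Fos are on both the immediate early and stress list and the FGF and ERK list. Of 18 immediate early and stress genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.000276, adjusted p = 0.518 with an estimated correlation), including Fosb at 3.53 ± 0.44. The number that rose was 5 without FGF-ESC replicate 1, 3 without ESC replicate 1 and 4 without ESC replicate 2. Of 16 p53 targets 6 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 1.22e-07, adjusted p = 0.397 with an estimated correlation), among them the death receptor Fas at 2.002 ± 0.235 and Plk2 at 2.58 ± 0.36. Here the count was 4 without FGF-ESC replicate 1, 3 without ESC replicate 1 and 2 without ESC replicate 2. Of 20 cell cycle genes 0 passed in limma, with a median of -0.34 and a camera adjusted p of 0.000735 (adjusted p = 0.618 with an estimated correlation). The median was -0.16 without FGF-ESC replicate 1, where the list passed, and fry, the rotation test, did not call it (adjusted p = 0.0648). Mcm5, a helicase subunit of DNA replication, had -0.85 ± 0.14, and -1.04 without FGF-ESC replicate 2, where it passed. On these arrays the fibroblast list was higher by a median of 3.37. Of 12 housekeeping controls 1 rose, B2m, with a median of -0.06 and a camera adjusted p of 0.945, for which the direction of the test was up.

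Against EpiSC, the question is whether lines kept in the same kind of FGF2 medium share the primed state. Naive genes were far higher in FGF-ESC. Klf4 rose by 3.83 ± 0.13 (8.52 against 4.69, n = 2 arrays per group, adjusted p = 1.45e-05), Tbx3 by 3.08 ± 0.14, Zfp42 by 2.77 ± 0.21, Dppa3, a maternal factor that protects DNA methylation, by 2.72 ± 0.26 and Tfcp2l1 by 2.13 ± 0.16. The nuclear receptors Nr5a2 and Nr0b1 rose by 2.01 ± 0.14 and 4.40 ± 0.32, and Prdm14 by 1.40 ± 0.20. Of 25 naive genes 22 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 1.86 and a camera adjusted p of 2.4e-19 (adjusted p = 0.262 with an estimated correlation). Of 18 LIF and STAT3 targets 12 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 2.82e-09, adjusted p = 0.245 with an estimated correlation), among them the receptor Lifr at 1.45 ± 0.14 and Bcl3 at 2.33 ± 0.23. These counts were 22 and 11 without FGF-ESC replicate 1, where the naive median was 2.07. The naive and LIF lists share Klf4, Klf5, Tfcp2l1 and Gbx2. Beside both lists, fibroblast genes were higher in FGF-ESC by a median of 2.79.

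Primed and gastrulation genes were lower in FGF-ESC than in EpiSC. Fgf5, a growth factor of the primed epiblast, was at 3.30 and 5.90, a log2 fold change of -2.60 ± 0.17 (adjusted p = 6.51e-05). The Nodal antagonists Lefty1 and Cer1 had -2.37 ± 0.16 and -3.33 ± 0.46, the growth factor Fgf8 -2.07 ± 0.20 and Enpp3 -1.99 ± 0.14. Of 22 primed genes 0 rose and 9 fell (0 and 10 adjusted over the list alone), with a median of -0.93 and a camera adjusted p of 5.3e-07 (adjusted p = 0.141 with an estimated correlation). Of 16 gastrulation genes 1 rose and 7 fell (1 and 7 adjusted over the list alone; camera adjusted p = 5.37e-05, adjusted p = 0.225 with an estimated correlation), led by the transcription factors Lhx1 at -2.40 ± 0.18, Mixl1 at -1.80 ± 0.21 and Eomes at -1.49 ± 0.18. Of 14 neural genes 0 rose and 4 fell (0 and 4 adjusted over the list alone; camera adjusted p = 0.0272, adjusted p = 0.262 with an estimated correlation), including Fabp7, a lipid-binding protein of radial glia, at -5.01 ± 0.32 and Sox1 at -1.87 ± 0.18. Of 13 Nodal targets 1 rose and 5 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.0115, adjusted p = 0.272 with an estimated correlation), among them Foxa2 at -1.501 ± 0.178. In a fit without FGF-ESC replicate 1 the medians were -0.85 for primed, -0.84 for gastrulation, -0.11 for neural and -0.495 for Nodal genes. The Nodal list shares Nodal, Lefty1 and Lefty2 with the primed list, and Cer1, Eomes, Foxa2 and Gsc with the gastrulation list. Its falls are thus in part those of the other lists. Beside these lists, the fibroblast median was 2.79 higher in FGF-ESC.

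Nanog and Pou5f1 did not separate FGF-ESC from EpiSC in this test, while other markers had an adjusted p below 0.05 but lay under or near the fold minimum. Nanog had -0.07 ± 0.21 (adjusted p = 0.862), and 0.29 without FGF-ESC replicate 1, and Pou5f1 -0.26 ± 0.12 (adjusted p = 0.163). Esrrb, at 0.66 ± 0.16 (adjusted p = 0.0241), was under the fold minimum. Sox2, which rose by 1.19 ± 0.20 (adjusted p = 0.00463), was under it without FGF-ESC replicate 2 (0.88). Otx2, at -0.86 ± 0.19 (adjusted p = 0.0153), missed only the fold minimum. It was past that minimum without FGF-ESC replicate 2 (-1.09) or EpiSC replicate 1 (-1.06). Dnmt3b, at -0.998 ± 0.141 (adjusted p = 0.00221), also missed only the minimum. It was past the minimum without FGF-ESC replicate 1 (-1.14) or EpiSC replicate 2 (-1.09). The FGF and ERK list, with 3 of 19 genes higher and 2 lower (3 and 2 adjusted over the list alone), had a median of 0.02 and a camera adjusted p of 0.579. The median was -0.03 without FGF-ESC replicate 1, and 6 genes were higher without FGF-ESC replicate 2. Beside it the fibroblast list was higher by a median of 2.79.

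Genes of the fibroblast list were again among the largest rises relative to EpiSC. Ifi204 rose by 5.56 ± 0.30 (adjusted p = 3.44e-05), Mmp3 by 5.52 ± 0.36, Lum by 5.23 ± 0.28, Ccl8 by 5.01 ± 0.24, Dcn by 5.01 ± 0.32, the matrix protein Postn by 4.69 ± 0.36, the angiotensin receptor Agtr2 by 4.53 ± 0.27 and the matrix protein Dpt by 4.51 ± 0.28. On the lower side stood the carbonic anhydrases Car2 at -4.73 ± 0.20 and Car4 at -2.98 ± 0.29, the trypsin inhibitor Spink1 at -3.85 ± 0.26, the zinc transporter Slc39a8 at -3.72 ± 0.17, the immunoglobulin superfamily protein Prtg at -3.17 ± 0.16 and the semaphorin Sema6a at -2.87 ± 0.30. In all 990 genes passed, 715 higher and 275 lower in FGF-ESC, and 945 without FGF-ESC replicate 1. Of 26 fibroblast genes 21 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 2.79 and a camera adjusted p of 7.89e-19 (adjusted p = 0.272 with an estimated correlation), among them the collagen cross-linking enzyme Lox at 3.59 ± 0.20 and Thy1 at 3.55 ± 0.22. Of these 20 rose without FGF-ESC replicate 1, with a median of 1.73 in place of 2.79.

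Parts of the mesenchymal, interferon, p53 and stress lists also rose relative to EpiSC. Of 15 mesenchymal transition genes 8 rose and 0 fell (9 and 1 adjusted over the list alone; camera adjusted p = 2.06e-06, adjusted p = 0.396 with an estimated correlation), with S100a4 at 3.83 ± 0.33 and fibronectin, Fn1, at 2.17 ± 0.20; the count was 6 without FGF-ESC replicate 1 and 13 without FGF-ESC replicate 2. Of 16 interferon and MHC genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.00181, adjusted p = 0.457 with an estimated correlation), with a median of 0.33, among them B2m at 1.501 ± 0.125 and Irf7 at 2.10 ± 0.35. Without FGF-ESC replicate 1, 2 of these rose, the median was -0.004 and the list's adjusted p was 0.141, with a range of 7.84e-07 to 0.141 over its alternatives. Of 16 p53 targets 7 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.000101, adjusted p = 0.396 with an estimated correlation), including Fas at 1.93 ± 0.23 and Trp53inp1 at 1.27 ± 0.14, and 3 rose without FGF-ESC replicate 1 or EpiSC replicate 1. Of 18 immediate early and stress genes 7 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.00108, adjusted p = 0.396 with an estimated correlation), such as Ddit3 at 1.48 ± 0.22 and Dusp1 at 1.36 ± 0.22, and 5 rose without FGF-ESC replicate 1. Other lists were lower. Of 20 cell cycle genes 0 passed in limma, with a median of -0.33 (camera adjusted p = 0.000903, adjusted p = 0.453 with an estimated correlation), and -0.17 without FGF-ESC replicate 1. Of 19 genes of cholesterol synthesis 0 rose and 2 fell, Msmo1 at -1.28 ± 0.14 and Hmgcs1 at -1.23 ± 0.14 (0 and 2 adjusted over the list alone; camera adjusted p = 2.21e-05, adjusted p = 0.262 with an estimated correlation). Beside each of these lists, fibroblast genes were higher by a median of 2.79. Of 12 housekeeping controls 1 rose, B2m, with a median of 0.02 and a camera adjusted p of 0.537.

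**Figure D4:**
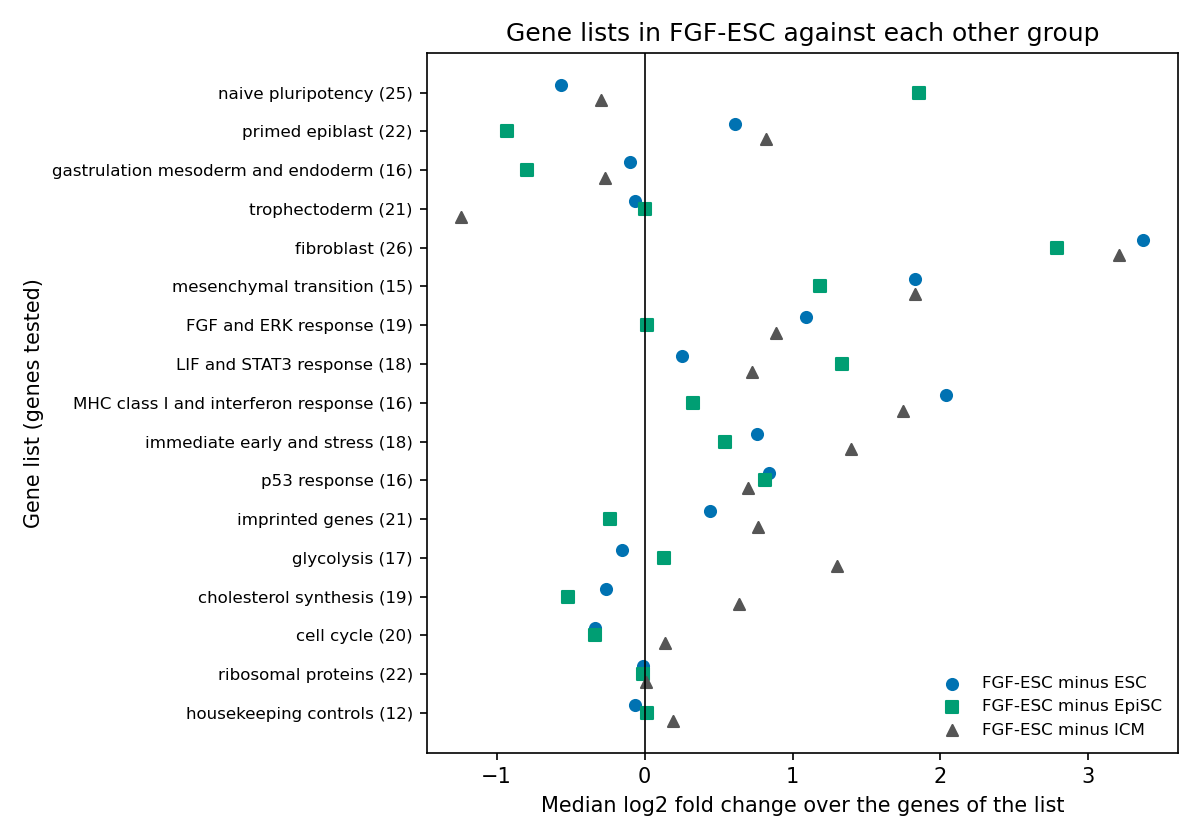
Median log2 fold change over the tested genes of 17 gene lists, for FGF-ESC minus ESC (circles), minus EpiSC (squares) and minus ICM (triangles), with the number of genes in brackets. The naive list has a median of -0.56 against ESC and 1.86 against EpiSC, and the fibroblast list is at 2.79 or above in all 3 comparisons.

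Against ICM, the question is how far the cultured lines stand from their tissue of origin. Naive genes moved in both directions. Dppa3 (probe set 17462686) was at 7.16 in FGF-ESC and 10.29 in ICM, a log2 fold change of -3.12 ± 0.26 (n = 2 arrays per group, adjusted p = 6.2e-05), while Nr0b1 rose by 4.42 ± 0.32. Nr5a2 had -2.01 ± 0.14, Pecam1 -1.95 ± 0.18, Zfp42 -1.45 ± 0.21, Tbx3 -1.41 ± 0.14 and Tfcp2l1 -1.28 ± 0.16, whereas Klf4 rose by 1.34 ± 0.13 and Sox2 by 1.47 ± 0.20. Of 25 naive genes 4 rose and 8 fell (4 and 8 adjusted over the list alone), with a median of -0.29 and a camera adjusted p of 0.406. Primed genes were higher: 9 of 22 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.00818, adjusted p = 0.352 with an estimated correlation), led by Sox4 at 4.06 ± 0.27 and the zinc finger gene Zic5 at 3.09 ± 0.35 (2.31 and 1.45 on their other probe sets), and Lefty1 was higher at 6.84 against 5.54 (SE of the difference 0.16, adjusted p = 0.000397). Without FGF-ESC replicate 1, 5 naive and 11 primed genes rose, and the naive median was on the other side of 0, at 0.04. Panel genes that did not pass were Nanog at -0.22 ± 0.21, and 0.14 without FGF-ESC replicate 1, Pou5f1 at -0.62 ± 0.12, Esrrb at 0.39 ± 0.16, Fgf5 at 0.29 ± 0.17, Cer1 at 0.40 ± 0.46 and Dnmt3b at 0.77 ± 0.14. Prdm14 was at 0.79 ± 0.20 and passed without FGF-ESC replicate 1 (1.04), and Otx2 was at -0.99 ± 0.19 and passed without FGF-ESC replicate 2 (-1.23) or ICM replicate 2 (-1.01). Fibroblast genes were higher in FGF-ESC by a median of 3.21 in this comparison.

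The largest falls in FGF-ESC were from high levels in ICM. The amino acid transporter Slc1a1 had a log2 fold change of -5.34 ± 0.15, the gluconeogenic enzyme Fbp2 -5.55 ± 0.12, the peptidase Enpep -5.22 ± 0.11 and Calcoco2 -5.63 ± 0.15 (adjusted p = 2.25e-07). Pramel5 at -6.00 ± 0.13, Khdc1a at -5.85 ± 0.20, Khdc1c at -5.08 ± 0.34 and Trim43a at -5.12 ± 0.13 belong to multigene families with near-identical copies, so which copy was read is uncertain. Of 21 trophectoderm genes 1 rose and 11 fell (1 and 11 adjusted over the list alone), with a median of -1.24 and a camera adjusted p of 0.000188 (adjusted p = 0.352 with an estimated correlation), among them the receptor Fgfr2 at -1.99 ± 0.17, the water channel Aqp3 at -1.78 ± 0.17 and the desmosomal protein Dsp at -2.49 ± 0.27. Of 18 epithelial genes 1 rose and 6 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.00383, adjusted p = 0.385 with an estimated correlation), including the tight junction gene Cldn7 at -1.90 ± 0.26 and the splicing regulator Esrp2 at -1.78 ± 0.15. Gata6, a factor of primitive endoderm on both the gastrulation and the primitive endoderm lists, had -4.39 ± 0.15. Of 19 primitive endoderm genes 2 rose and 4 fell (2 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0748). It passed without FGF-ESC replicate 1 (0.00438) and with arrays centred on their median (0.0478), with a range of 0.00438 to 0.398 over its alternatives. Of 16 gastrulation genes 1 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.0455, adjusted p = 0.352 with an estimated correlation), and this list did not pass without FGF-ESC replicate 2 (0.109), without ICM replicate 2 (0.101) or after quantile normalization (0.0501). Without FGF-ESC replicate 1, 11 trophectoderm and 6 epithelial genes fell, and the trophectoderm median was -1.12. Beside these lists, fibroblast genes were higher by a median of 3.21. The trophectoderm list also passed camera for ESC with ICM (adjusted p = 0.00223) and for EpiSC with ICM (0.000267). The primitive endoderm list passed camera in both as well (0.00223 and 0.000505), and so did the epithelial list (0.014 and 0.000704). A difference from ICM in the trophectoderm or epithelial list was therefore not particular to FGF-ESC. These 2 lists share Krt8, Krt18, Krt19, Cldn4 and Dsp. The trophectoderm list was fixed to mark trophectoderm left after immunosurgery, which was not tested further.

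Genes of glycolysis and cholesterol synthesis were higher in FGF-ESC than in ICM. Pdk1, a kinase that restrains pyruvate oxidation, rose by 5.31 ± 0.17 (adjusted p = 5.5e-07) from an ICM level of 3.58, and by 1.85 on its other probe set, from 4.72. The glycolytic enzymes Tpi1 and Pgk1 rose by 2.08 ± 0.12 and 1.95 ± 0.14, and the lactate dehydrogenase Ldhb by 3.47 ± 0.29. Of 17 glycolysis genes 9 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 1.6e-08, adjusted p = 0.352 with an estimated correlation). Of 19 cholesterol synthesis genes 7 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.0013, adjusted p = 0.352 with an estimated correlation), among them the regulator Srebf2 at 1.20 ± 0.12 and Fdft1 at 1.21 ± 0.13. Without FGF-ESC replicate 1 these counts were 10 and 5. Other metabolic lists did not pass: of 29 oxidative phosphorylation genes 0 rose and 1 fell (camera adjusted p = 0.406), and of 17 genes of fatty acid synthesis and storage 4 rose and 4 fell (camera adjusted p = 0.989). Fibroblast genes were higher by a median of 3.21 beside the glycolysis and cholesterol lists. These lists also passed camera for ESC with ICM (adjusted p = 6.37e-10 for glycolysis and 3.34e-05 for cholesterol synthesis). They passed for EpiSC with ICM as well (1.76e-06 and 4.91e-07). A difference from ICM in these lists was therefore not particular to FGF-ESC.

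Fibroblast, interferon, FGF and ERK, immediate early and mesenchymal genes also rose against ICM. The membrane protein Emp1 rose by 7.12 ± 0.32 (adjusted p = 2.52e-06), from an ICM level of 2.84, and by 3.12 on its other probe set. Ccl2 rose by 7.03 ± 0.26, Col1a2 by 6.93 ± 0.23 (3.76 on its other probe set), Dcn and Lum by 6.49 ± 0.32 and 6.49 ± 0.28, Mmp3 by 6.44 ± 0.36, and Anxa1 and the chemokine Ccl7 by 6.21 ± 0.38 and 6.21 ± 0.27. Of 26 fibroblast genes 25 rose and 0 fell (25 and 0 adjusted over the list alone), with a median of 3.21 and a camera adjusted p of 1.98e-14 (adjusted p = 0.352 with an estimated correlation). Of 16 interferon and MHC genes 11 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 4.87e-07, adjusted p = 0.352 with an estimated correlation), with Ifitm3, an antiviral membrane protein, at 5.52 ± 0.14. Of 19 FGF and ERK targets 8 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 6.52e-06, adjusted p = 0.352 with an estimated correlation), with Egr1 at 3.65 ± 0.23 and the feedback inhibitor Spry4 at 2.21 ± 0.22. Of 18 immediate early genes 12 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 7.26e-06, adjusted p = 0.352 with an estimated correlation), and of 15 mesenchymal genes 11 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 3.47e-07, adjusted p = 0.37 with an estimated correlation). Without FGF-ESC replicate 1 the counts of these 5 lists, in the order given, were 23, 9, 8, 9 and 9, and the fibroblast median was 2.28. Of 16 p53 targets 5 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.00358, adjusted p = 0.474 with an estimated correlation), 2 without FGF-ESC replicate 1 and 3 without ICM replicate 1. Response lists of WNT (3 rose and 2 fell, camera adjusted p = 0.486), BMP (2 and 1, 0.712) and Nodal (4 and 2, 0.201; 2 and 2 without ICM replicate 1) did not pass. In all 2011 genes passed, 1301 higher and 710 lower, and 1822 without FGF-ESC replicate 1. Of 12 housekeeping controls 2 rose, B2m and Pgk1, and 1 fell, Hprt at -1.35 ± 0.13, with a median of 0.19 and a camera adjusted p of 0.273. Cultured cells and ICM also differed in the RNA extraction kit.

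The ESC and EpiSC samples show how far the naive and primed references lay apart. Tbx3 rose by 4.20 ± 0.14 in ESC relative to EpiSC (n = 2 arrays per group, adjusted p = 4.16e-06), Zfp42 by 4.05 ± 0.21, Klf4 by 3.90 ± 0.13 and Tfcp2l1 by 3.88 ± 0.16, and Dppa3, Prdm14, Sox2 and Esrrb also passed, at 2.45 ± 0.26, 1.67 ± 0.20, 1.38 ± 0.20 and 1.21 ± 0.16. The largest rises were Mylpf, a myosin light chain, at 4.86 ± 0.28, Gtsf1l at 4.76 ± 0.41, Lrrc34 at 4.59 ± 0.31 and Fbxo15 at 4.42 ± 0.45. Lower in ESC were Fabp7 at -5.28 ± 0.32, Spink1 at -4.94 ± 0.26, Rtp4 at -4.86 ± 0.35, Car2 at -4.78 ± 0.20, Cer1 at -3.67 ± 0.46, Lefty1 at -3.18 ± 0.16, Fgf5 at -2.81 ± 0.17 and Dnmt3b at -1.996 ± 0.141. Otx2, at -1.07 ± 0.19 (adjusted p = 0.00525), did not pass without ESC replicate 2 (adjusted p = 0.052, range 0.000301 to 0.052 over its alternatives) or EpiSC replicate 2 (-0.87). Nanog, at 0.91 ± 0.21, and Pou5f1, at 0.23 ± 0.12, did not pass.

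Of 25 naive genes 23 rose and 1 fell in ESC (23 and 1 adjusted over the list alone; camera adjusted p = 2.13e-23, adjusted p = 0.251 with an estimated correlation). Of 22 primed genes 1 rose and 15 fell (1 and 15 adjusted over the list alone; camera adjusted p = 5.72e-12), and this list also passed with an estimated correlation (adjusted p = 0.0465). Of 19 FGF and ERK targets 0 rose and 7 fell (0 and 7 adjusted over the list alone; camera adjusted p = 1.63e-07, adjusted p = 0.272 with an estimated correlation), such as Dusp6 at -2.17 ± 0.12 (-3.86 on its other probe set) and Egr1 at -2.32 ± 0.23. Of 16 interferon and MHC genes 0 rose and 7 fell (0 and 7 adjusted over the list alone; camera adjusted p = 4.07e-05, adjusted p = 0.379 with an estimated correlation), such as Psmb9 at -1.55 ± 0.18 and H2-K1 at -1.95 ± 0.21. Of 26 fibroblast genes 0 rose and 6 fell (0 and 6 adjusted over the list alone; camera adjusted p = 0.0012, adjusted p = 0.733 with an estimated correlation), with Col1a2 at -3.43 ± 0.23 (-0.43 on its other probe set) and Mmp2 at -3.04 ± 0.29, and 2 fell without ESC replicate 1, ESC replicate 2 or EpiSC replicate 2. The fibroblast list had a median of -0.46 beside all of these lists. In all 1001 genes passed, 476 higher and 525 lower in ESC, and 0 of 12 housekeeping controls passed in limma, with a camera adjusted p of 0.935.

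Between these references, FGF-ESC replicate 1 lay about midway and replicate 2 nearer to ESC. On a scale of 0 at ESC and 1 at EpiSC the FGF-ESC arrays were at 0.493 and 0.343 (mean 0.418 ± 0.106, SD, n = 2), and the ICM arrays at 0.183 and 0.190 (mean 0.187 ± 0.0048, SD, n = 2). Across all tested genes replicate 1 correlated less with the ESC arrays (0.876 and 0.877) than with the EpiSC arrays (0.884 and 0.896), and replicate 2 more (0.939 and 0.940 against 0.918 and 0.927). Of the 476 genes higher in ESC than in EpiSC, the FGF-ESC mean was closer to ESC for 308, or 64.7%, and of the 525 genes higher in EpiSC it was closer to ESC for 278, or 53%. Of the first set, 195 differed in FGF-ESC from EpiSC alone, 64 from ESC alone, 38 from both and 179 from neither. For the second set these counts were 181, 142, 47 and 155. Over the naive and primed lists alone the FGF-ESC position was 0.275 and that of ICM 0.0827. The position over all axis genes takes in fibroblast signal, which was lower in ESC than in EpiSC for 6 of the 26 markers, Col1a2 on only 1 of its 2 probe sets.

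Differences of FGF-ESC and EpiSC from ESC overlapped. Both were higher than ESC for 189 genes, both were lower for 94, and 8 genes moved in opposite directions. FGF-ESC and ESC were both higher than EpiSC for 233 genes, both lower for 197 and opposite for 31. They were both higher than ICM for 529 genes, both lower for 504 and opposite for 12. Fold changes that share a group are correlated even where no group differs. The correlation across genes was 0.483, 0.491 and 0.708 (Spearman 0.505, 0.49 and 0.717), against 0.501, 0.501 and 0.499 in simulations of unchanged groups. Noise alone sets that simulated level, whatever the data. It therefore does not show how much of a measured correlation comes from sharing a group. Covariances were 0.186, 0.189 and 0.455 against a simulated 0.0154, 0.0154 and 0.0153. With 1 array of the shared group in each comparison, a choice made after the data were seen, the array noise of that group no longer enters both. Whatever else is particular to the shared group still does. The correlation was then 0.453 and 0.455 against ESC, 0.48 and 0.42 against EpiSC, and 0.653 and 0.652 against ICM, by which array served FGF-ESC. Both fits also take the spread from the same arrays of the other groups. The counts from independent draws are therefore given for scale and are not a level due to chance. Against ESC 86 and 88 genes were then higher in both, by which array served FGF-ESC, where independent draws give 9.4 and 10.2, and 47 and 58 lower (2.1 and 2.4). Against EpiSC 200 and 209 were higher (17.7 and 18) and 169 and 167 lower (7.9 and 8.7), and against ICM 488 and 462 were higher (74.5 and 75.6) and 452 and 471 lower (39.5 and 39.5).

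ESC and EpiSC were each compared with ICM as background. In ESC Bex1 rose by 5.96 ± 0.33 (n = 2 arrays per group, adjusted p = 8.96e-06), the microtubule regulator Stmn2 by 5.47 ± 0.14, Plagl1 by 5.43 ± 0.40 (1.57 on its other probe set) and the Y RNA gene Rny3 by 5.42 ± 0.21, and falls were led by Pramel5 at -5.86 ± 0.13, Fbp2 at -5.65 ± 0.12, Khdc1a at -5.29 ± 0.20 and the phosphatase Alppl2 at -5.19 ± 0.12, with the same doubt over copies for Pramel5 and Khdc1a. Sox2 rose by 1.65 ± 0.20 and Klf4 by 1.42 ± 0.13, while Dppa3 was at -3.40 ± 0.26 and Otx2 at -1.20 ± 0.19. Of 17 glycolysis genes 11 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 6.37e-10, adjusted p = 0.312 with an estimated correlation), including Pdk1 at 4.92 ± 0.17 (1.70 on its other probe set) and Tpi1 at 2.49 ± 0.12. Of 26 fibroblast genes 1 rose and 1 fell (camera adjusted p = 0.777), and of 12 housekeeping controls 3 rose and 1 fell (camera adjusted p = 0.352). In all 1548 genes passed, 791 higher and 757 lower in ESC.

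In EpiSC relative to ICM, Bex1 rose by 6.03 ± 0.33, Stmn2 by 5.43 ± 0.14, Car2 by 5.34 ± 0.20 and Fabp7 by 5.23 ± 0.32, and Calcoco2 was at -7.23 ± 0.15, Pramel5 at -5.91 ± 0.13, Dppa3 at -5.84 ± 0.26 and Fbxo15 at -5.67 ± 0.45. Of 25 naive genes 1 rose and 16 fell (1 and 16 adjusted over the list alone; camera adjusted p = 7.75e-10, adjusted p = 0.321 with an estimated correlation), with Tbx3 at -4.49 ± 0.14 and Nr5a2 at -4.01 ± 0.14. Of 22 primed genes 13 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 1.75e-06, adjusted p = 0.142 with an estimated correlation), with Lefty1 at 3.67 ± 0.16 and Enpp3 at 3.18 ± 0.14. Of 26 fibroblast genes 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.32 and a camera adjusted p of 0.0259 (adjusted p = 0.711 with an estimated correlation). That list did not pass without EpiSC replicate 2 (adjusted p = 0.0542) or ICM replicate 1 (adjusted p = 0.0612), with a range of 0.0128 to 0.0612 over its alternatives. Of 12 housekeeping controls 2 rose and 1 fell (camera adjusted p = 0.263). In all 2078 genes passed, 1153 higher and 925 lower in EpiSC.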

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

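The tests of explanations in this part were chosen only after the results were seen.

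The fibroblast genes that rose in FGF-ESC relative to the other groups could come from RNA of other cells in the sample, such as the feeder fibroblasts. FGF-ESC replicate 1, which had the higher fibroblast level (8.54 against 7.27), had lower pluripotency genes: the median difference between the arrays over 41 core and naive genes was -0.349, with 39 of 41 lower in replicate 1, against 0.019 in ESC, -0.19 in EpiSC and -0.125 in ICM. The FGF-ESC difference is what a larger share of other RNA in replicate 1 would give, and Col1a2 at 10.05 (8.09 on its other probe set) and Thy1 at 9.80 in FGF-ESC show how abundant the markers were. In EpiSC and ICM, however, replicate 1 also had the lower fibroblast level (5.09 against 5.32, and 4.33 against 4.46). Smaller differences of that sign thus arose there without more fibroblast signal. A part of the FGF-ESC cells turning mesenchymal would lower the same genes and was not tested, and neither was a feeder state that differs between FGF-ESC and EpiSC cultures. The labels name no step that removed feeders, and all of these differences run with the group.

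For the naive genes lower in FGF-ESC than in ESC, dilution by such RNA would lower every gene well above background by about one amount. Over 16 naive genes at 7 or more in ESC the changes had an SD of 0.542, against a root mean square SE of 0.233. The SD only narrowly passed the multiple of that SE set as the rule. Changes ran from -1.75 for Tfcp2l1 to -0.01 for Nr0b1 (SE 0.32) and -0.20 for Fgf4, which ranged from -0.48 to 0.092 over left-out arrays. This argues only weakly against dilution as the whole cause, since the SE pools all groups and FGF-ESC had the largest spread. Fibroblasts themselves express Klf4 and Klf5, which may hide a dilution of these genes (-0.07 and -0.09). Dilution as a part of the cause stays open. So does the culture the design names, FGF2 and feeders in place of LIF and the inhibitors, as untested; the labels give day 3.5 embryos as the origin of both.

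Interferon-response genes were also higher in EpiSC than in ESC, and a lower share of the same fibroblast RNA could account for that. The excess over ESC in FGF-ESC relative to that in EpiSC had a median log2 ratio of 0.547 over the 7 interferon genes (-0.34 to 2.64) and 3.89 over the 6 fibroblast genes (0.94 to 5.96) that were higher in EpiSC, with an exact rank-sum p of 0.00816 (two-sided; 0.0177 without Col1a2, whose other probe set was nearly level between ESC and EpiSC). The genes were read on the same arrays and are not independent replicates, so this p does not measure the spread between samples. In EpiSC Lum was at 4.225, near background, and Dcn at 4.76, which can inflate their ratios. The test therefore cannot decide whether RNA of the profile seen in FGF-ESC is the whole cause. A stricter rule tried first, that the sets be fully apart, was not met, since their ranges overlap; both sets were also picked for being higher in EpiSC. Feeder RNA of another profile, the absence of LIF and the inhibitors, and the EpiSC state itself stay open too, as untested.

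Probe sets with no listed gene were outside the comparisons, and among 7546 of them tested in the same way 114 were higher and 121 lower in FGF-ESC than in ESC, 147 higher and 163 lower than in EpiSC, and 372 higher and 674 lower than in ICM. Among 1333 probe sets listed with several genes, 47 were higher and 28 lower than in ESC, 85 higher and 53 lower than in EpiSC, and 175 higher and 83 lower than in ICM. These signals drew attention because they lie in values that no gene comparison used.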

How the results depend on the processing

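Counts of list members without FGF-ESC replicate 1, and overlaps with 1 array of the shared group in each comparison, were added after the results were seen; the other alternatives were planned. Results were recomputed under each alternative. Genes passing between FGF-ESC and ESC numbered 844, and 526 in a fit of these groups alone, 521 at an adjusted p under 0.01, and 374 to 1287 with 1 array left out. Fits of the compared groups alone gave 775 against 990 for FGF-ESC with EpiSC, but 1034 against 1001 for ESC with EpiSC, at the same loss of residual degrees of freedom. The residual SD was 0.279 in FGF-ESC and 0.124 in ESC, 0.151 in EpiSC and 0.208 in ICM. Leaving out an ESC array takes the group with the smallest spread out of the shared estimate. Leaving out an FGF-ESC array takes out the group with the largest. Counts over left-out arrays depend in part on this by construction. Without FGF-ESC replicate 1, however, fewer genes passed in each comparison of FGF-ESC, although its group has the largest spread. The shared estimate alone therefore does not set these counts. Other causes, and the cause of the lower counts in fits of the compared groups alone, were not tested. The ranges with 1 array left out were 747 to 1287 against EpiSC, 1822 to 2270 against ICM, 848 to 915 for ESC with EpiSC, 1410 to 1584 for ESC with ICM and 2009 to 2099 for EpiSC with ICM; a group left with 1 array was assumed to vary like the others. By construction, dropping the minimum fold change gave more genes (2087, 2692 and 4984 for FGF-ESC with ESC, EpiSC and ICM, the first as 1256 higher and 831 lower, 2584 for ESC with EpiSC, 4488 for ESC with ICM and 5219 for EpiSC with ICM), and a test of the fold minimum itself (treat) gave fewer (167, 238, 724, 307, 466 and 862 in that order). Counting every probe set on its own, which tests more features, gave 1072 for FGF-ESC with ESC (781 higher and 291 lower, against 717 and 127), 3440 for FGF-ESC with ICM, 1579 for ESC with EpiSC, 2969 for ESC with ICM and 3543 for EpiSC with ICM.

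Among gene lists, 11, 16, 15 and 16 passed camera for FGF-ESC with ESC, EpiSC and ICM and for ESC with EpiSC, against 0, 0, 0 and 1 with an estimated correlation. That setting also tests on the 4 residual degrees of freedom, so the lower counts cannot be credited to dependence between genes alone. The rotation test fry, which does not compare a list with other genes, called 25 against ICM. The FGF-ESC position was 0.275 over the naive and primed lists alone, 0.474 and 0.421 with axis genes at a log2 difference of 1 and 3, and 0.428 after quantile normalization, and the ICM position was 0.0827, 0.193, 0.171 and 0.194 in that order; the cause was not tested. With 1 array of the shared group in each comparison, genes higher in both FGF-ESC and EpiSC than in ESC numbered 86 and 88, against 189 with both arrays, where fewer arrays also give fewer calls.

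Genes followed here were the largest rises and falls, the panel and the members with the smallest adjusted p of every list, described or not. Apart from the panel they were picked for large or clear changes, so much of their stability was set by that choice. Most kept their direction and their side of the threshold. Of 718 results, 718 did with trended and robust moderation, 717 with array weights and 717 with a replicate block. In fits of the compared groups alone 709 did. Of 714 results 707 did after quantile normalization and 707 after centring, which shifted the median of all genes by at most 0.072. Without FGF-ESC replicate 1, 396 of 425 did, and without FGF-ESC replicate 2, 395 of 425. The results that reversed were all short of the threshold, did so when 1 array was left out, and the cause was not tested. Against ESC, over the left-out arrays, FGF-ESC changes ranged from -0.50 to 0.13 for Sox2, -0.41 to 0.24 for Tyrobp, -0.30 to 0.006 for Tmem92, -0.034 to 0.18 for Zscan4d (-0.023 without ESC replicate 2), -0.48 to 0.092 for Fgf4, -0.11 to 0.66 for Dppa3 and -0.026 to 0.45 for Otx2. Nanog ranged from -0.43 to 0.29 against EpiSC and -0.59 to 0.14 against ICM, and Tyrobp from -0.29 to 0.37 against EpiSC (-0.033 without EpiSC replicate 1). Between the other groups, Zfp352 ranged from -0.001 to 0.36 for ESC with EpiSC, Cer1 from -0.078 to 0.20 and Fgf5 from -0.067 to 0.21 for ESC with ICM, and Otx2 from -0.34 to 0.067 for EpiSC with ICM. Signal over background limits dim genes: Fgf5, at 3.01 to 3.30 in FGF-ESC, ESC and ICM, lay below the median of all values there, so differences between these groups could not be read.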

Other observations

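Every observation in this part was chosen after the values were seen, from lists fixed before. Xist, the RNA that coats the inactive X chromosome, was at 7.96 in FGF-ESC, 4.39 in ESC, 4.06 in EpiSC and 9.31 in ICM. It rose in FGF-ESC by 3.57 ± 0.23 (SE, n = 2 arrays per group, adjusted p = 8.01e-05) relative to ESC and by 3.90 ± 0.23 (adjusted p = 4.62e-05) relative to EpiSC, and had a log2 fold change of -1.36 ± 0.23 (adjusted p = 0.00209) against ICM. Y-linked Eif2s3y was at 6.22, 5.30, 7.14 and 7.08 in the same order, and Y-linked Uty at 4.91, 5.17, 6.24 and 4.90, in FGF-ESC and ICM not far above the median of all values, 4.24. Y-linked Kdm5d and Usp9y were too dim to test. The FGF-ESC arrays also held fibroblast signal at a mean of 8.54 and 7.27. The sexes of the lines, the embryos and the feeders are not in the labels used here.

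Imprinted genes that passed went both ways relative to EpiSC, and mostly up relative to ICM and ESC. In FGF-ESC relative to EpiSC, Nnat rose by 3.57 ± 0.27 (adjusted p = 0.000124; 1.71 on its other probe set), while Peg10 had a log2 fold change of -1.61 ± 0.17, Mest of -1.24 ± 0.14 and Grb10 of -1.24 ± 0.15. Of 21 imprinted genes 3 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.179). Against ICM 9 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 6.51e-05, adjusted p = 0.293 with an estimated correlation), led by Peg3 at 2.52 ± 0.11 and Phlda2 at 3.79 ± 0.24, and 8 rose without FGF-ESC replicate 1. Against ESC 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0146, adjusted p = 0.397 with an estimated correlation), among them Igf2, a fetal growth factor, at 1.54 ± 0.20; 2 rose without ESC replicate 1 and 1 without ESC replicate 2. Fibroblast genes were higher in FGF-ESC by medians of 2.79, 3.21 and 3.37 in these comparisons. The imprinted list also passed camera for ESC with ICM (adjusted p = 0.014) and for EpiSC with ICM (6.44e-05).

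Germline genes that depend on DNA methylation were higher in FGF-ESC than in EpiSC. The synaptonemal complex gene Sycp1 rose by 2.48 ± 0.19 (adjusted p = 0.000124), the germ cell helicase Ddx4 by 1.84 ± 0.20, Hormad1 by 2.93 ± 0.32 and Rpl10l by 3.26 ± 0.35, the last from a family of near-identical copies. Of 14 such genes 5 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 1.85e-05, adjusted p = 0.262 with an estimated correlation), and 6 rose without FGF-ESC replicate 1. Of the same list 3 also rose in ESC relative to EpiSC (camera adjusted p = 0.0117, adjusted p = 0.379 with an estimated correlation). Against ESC 2 rose and 0 fell in FGF-ESC (camera adjusted p = 0.00648, adjusted p = 0.518 with an estimated correlation), and the list did not pass without FGF-ESC replicate 2 (0.0911, range 0.000534 to 0.0911 over its alternatives). Hormad1, 1 of these 2 genes (1.42 ± 0.32, adjusted p = 0.0217), did not pass without FGF-ESC replicate 2 (0.89), ESC replicate 1 (adjusted p = 0.168) or ESC replicate 2 (adjusted p = 0.0725), with a range of 0.000978 to 0.168 over its alternatives. It was also 1 of the 3 in ESC relative to EpiSC (1.51 ± 0.32, adjusted p = 0.0124), and did not pass there without ESC replicate 2 (0.109), EpiSC replicate 1 (0.0858) or EpiSC replicate 2 (0.0617), with a range of 0.000496 to 0.109. Against ICM 3 rose and 6 fell, with a median of -0.36 (camera adjusted p = 0.209), and 3 fell without ICM replicate 1. Fibroblast genes were higher in FGF-ESC by medians of 2.79, 3.37 and 3.21 relative to EpiSC, ESC and ICM.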
